A study of Mus musculus with 8 samples.

How the data were processed

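RNA from 8 mouse cell samples was measured on 8 Affymetrix expression arrays, 1 array per sample. The samples were 3 arrays of the parental neural crest precursor line JoMa1, 1 array of JoMa1 labelled as transfected with a GFP control, and 4 arrays of lines derived from tumours that MYCN-transfected JoMa1 cells had formed. Per the labels' protocols, cells were lysed in Trizol before reaching confluence, RNA was purified on RNeasy columns and the target was labelled with biotin. Groups and array numbers were taken from the titles, source names and transfectant labels. The source names and descriptions give independent tumours, while the cell line labels, the design text and the harvest from culture describe lines derived from tumours, and they are treated as lines here. The tumour lines carry the numbers 3 to 6, and those numbers are used here.

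The deposited table holds 1 log2 value per probe set and array, made by the authors with RMA, which subtracts background, normalizes the arrays to a shared distribution and summarises the probes of each probe set. RMA and Partek are named, per the submitters' processing notes, without versions. The log2 scale was read from the deposited values, whose array medians lay between 6.26 and 6.30. The genome build is not given in the sources used here. RMA pulls weak signals towards a common floor and normalizes away any change in total RNA, so that differences of dim genes are understated and levels are relative to the whole array. Detection calls and scanner intensities were not used here.

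Of the 45101 probe sets, 64 were controls, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 carried none. The last 2 kinds and the controls were left out of the gene tests. Gene IDs were looked up in a RefSeq gene table of the mouse assembly GRCm38.p6, which held 34741 of the probe sets' IDs, and 0 symbols changed. Each of the 18193 genes took its probe set with the highest mean over all 8 arrays. For 1626 genes this was a probe set of the kind that can bind several transcripts (suffix _x_at or _s_at). Among the 9010 genes with more than 1 probe set, 118 had probe sets called in opposite directions. No coordinates are printed, and the RefSeq table served only for names and for the order of genes along chromosomes.

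Comparisons used limma (version 3.58.1, in R 4.3.3) with lmFit and eBayes, 1 coefficient per group over all 8 arrays, two-sided tests and Benjamini-Hochberg adjustment over all 18193 genes. A gene was called at an adjusted p under 0.05, and counted again with a change of at least 2-fold. Errors beside differences are standard errors (SE) from this fit. The single array labelled GFP-transfected adds nothing to the residual spread and was assumed to vary like the other groups. The labels call the 4 tumours independent, but nothing states that the parental arrays came from separate cultures, so their part of the spread behind the p-values may be technical. Independent tumours may still share a transfected stock of cells. The p-values would then compare that stock with the parental cells. The number of arrays limits the precision.

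In total 32 gene lists were fixed from textbook knowledge. For tumour lines against parental cells they were tested with limma's camera (inter-gene correlation 0.01, Benjamini-Hochberg over the lists), with camera under an estimated correlation and with fry as alternatives. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. For comparisons with the single array, the median of each list was ranked among 10000 random lists of the same size, matched on mean level in 20 bins, which describes these arrays and is no test. Overlaps between comparisons that share arrays were set beside 20 simulations without effects. For the pair that shares the 4 tumour lines, these were also split into 2 and 2 in all 6 ways and fitted as separate groups, a test added after seeing the data.

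Named genes followed a rule. It took a set of anchors given whatever the test, and the 8 largest rises and 8 largest falls among called genes whose tumour lines all lay beyond all parental arrays. It took up to 3 called members of each list with the largest change and, for a called list, up to 1 member going against it. Each comparison with the array labelled GFP-transfected gave the 5 largest rises and 5 largest falls, and the tumour lines gave the 8 genes of largest SD. Names of unnamed transcripts were left out. Some fixed list members and anchors had no probe set of their own among those used and were not analysed here. The groups, designs, lists, named-gene rule and most alternatives were set before the data were examined.

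The alternatives were the mean of a gene's probe sets, every probe set tested singly, leaving out _x_at and _s_at probe sets, genes above the median mean level, a trended and robust variance prior, array weights, repeated quantile normalization, centring each array on its median, pooling the array labelled GFP-transfected with the parental arrays, fitting only parental and GFP-labelled arrays, an adjusted p under 0.01, a minimum of 2-fold, and leaving out each array in turn. Leaving the array labelled GFP-transfected out of the fit, and centring in the comparison of tumour lines with it, were added after seeing the data. The procedure was tested on simulated data with 50 changed genes at each size among 18193. For tumour lines against parental it recovered 54% at a log2 change of 0.5, 98% at 1, and 100% at 2 and at 3. For the array labelled GFP-transfected against parental it recovered 8%, 86%, 100% and 100% at those sizes. In that simulation 6 unchanged genes were called. It drew every array of a gene with the same spread and genes independently of each other. In the data the median SD of a gene was 0.08 in parental arrays and 0.128 in tumour lines. These shares therefore hold only under the simulated setting. Figures and neighbour tests used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.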

Results

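Expression was profiled in JoMa1, a mouse neural crest precursor cell line, and in lines grown out of tumours that JoMa1 formed after transfection with MYCN, the transcription factor gene amplified in high-risk neuroblastoma. The set held 3 parental arrays, 1 array labelled as a GFP transfection control and 4 tumour-line arrays, numbered 3 to 6. Levels are RMA values on the log2 scale, and ± gives the SD over the arrays of a group. The array medians, which RMA sets alike, ran from 6.26 to 6.30. The difference between 3' and 5' probe sets, a sign of RNA quality, was 0.626 to 0.641 for Actb in parental arrays and 0.516 to 0.613 in tumour lines. For Gapdh it was 0.053 to 0.078 and 0.092 to 0.151, so that the groups were apart in both genes, in opposite directions. The hybridisation control bioB read 7.70 on parental array 3 and 8.86 to 9.17 on the other arrays. The added poly-A controls averaged 8.28 on tumour line 3 and 7.62 to 7.86 elsewhere. The bacterial trpnX controls read 3.84 to 4.04, and values near that level carry little signal.

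The transfected gene was read first. The Mycn probe set with the highest signal stood at 7.42 ± 0.12 in the 3 parental arrays and at 14.17 ± 0.08 in the 4 tumour lines, a difference of 6.74 (SE 0.08, 107-fold). In limma the adjusted p was 1.79e-09. Another Mycn probe set, bright in parental cells, went the opposite way, with a difference of -3.53 and an adjusted p of 3.48e-08 in limma. The remaining probe set of Mycn differed by 0.30 (adjusted p = 0.0785). The library labelled GFP-transfected read 11.73 with the brightest probe set, 4.31 above the parental mean (SE 0.12, 19.8-fold, limma adjusted p = 7.68e-07). It read 4.33 with the one that went the opposite way, a difference of -3.80. Its Mycn signal therefore goes against its label, since a GFP control should carry no added MYCN, and every direction drawn from that library below has this limit. Averaged over its 3 probe sets, Mycn in that library differed by 0.21 (adjusted p = 0.164), within a range of 7.74e-07 to 0.768 over the alternatives. Where the transcript each probe set binds lies relative to the transfected sequence was not analysed here. Whether the transfected MYCN was human or mouse is not given in the sources used here, so how far these mouse probe sets measure it is not known here.

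**Figure D1:**
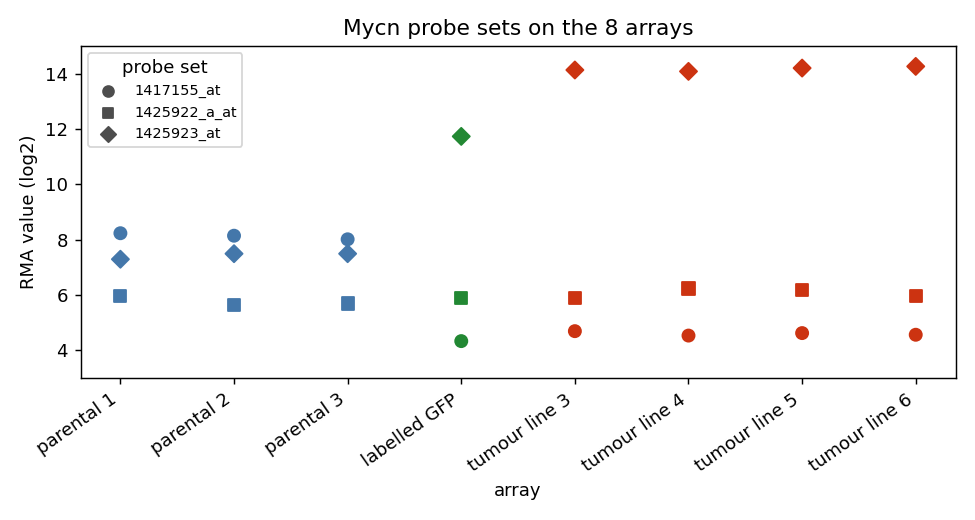
RMA values (log2, vertical axis) of the 3 Mycn probe sets on each of the 8 arrays (horizontal axis), with 1 marker shape per probe set and 1 colour per group. The brightest probe set (diamonds) reads 14.08 to 14.26 in the tumour lines, 11.73 in the library labelled GFP-transfected and 7.29 to 7.49 in the parental arrays, while the one drawn as circles is lower in the tumour lines and in that library than in parental cells.

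The main question was how lines from MYCN-induced tumours differ from the precursor cells they came from. The largest fall was that of Bex1, a small adaptor protein gene of the nervous system, from 12.97 ± 0.01 in 3 parental arrays to 3.72 ± 0.10 in 4 tumour lines (605-fold). The tumour-line value lies at the level of the trpnX controls. Among genes for chains of the basement membrane collagen IV, Col4a1 fell by 137-fold (-7.10, SE 0.10) and Col4a2 by 72.5-fold (-6.18, SE 0.08). The amino acid transporter gene Slc38a4 (-6.98, SE 0.37), the plasminogen activator inhibitor gene Serpinb2 (-5.65, SE 0.36), Nrep (-5.54, SE 0.17), Tmem47 (-5.46, SE 0.36) and the homeobox gene Hoxa9 (-5.37, SE 0.69) fell as well. After Mycn, the largest rises were those of Dynap (6.60, SE 0.26), the G-protein regulator gene Rgs2 (6.55, SE 0.24), Pate14 (6.52, SE 0.23), the protease inhibitor gene Slpi (6.20, SE 0.14), the iron-siderophore binding lipocalin gene Lcn2 (6.19, SE 0.33), the small GTPase gene Gem (5.94, SE 0.22) and the nuclear receptor gene Rorb (5.89, SE 0.11). Their limma adjusted p-values were 3.52e-06 or lower for the rises and 0.000443 or lower for the falls. Another probe set of Rgs2 differed by 0.04 and was not called. The library labelled GFP-transfected also differed from parental arrays, by -4.93 for Nrep and by 3.83 for Dynap. Tumour lines differed from that library by -0.60 for Nrep and by 2.77 for Dynap. The fall of Nrep was therefore not particular to the tumour lines.

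**Figure D2:**
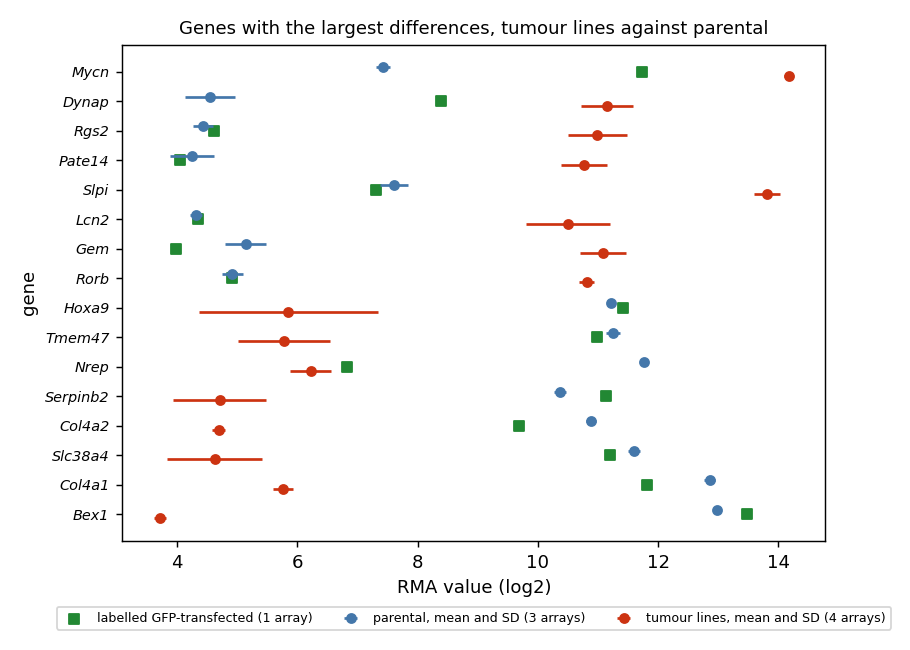
RMA values (log2, horizontal axis) of the 16 genes with the largest rises and falls in tumour lines against parental cells (vertical axis), as mean and SD over 3 parental and 4 tumour-line arrays, with the value of the library labelled GFP-transfected as a square. Bex1 drops from 12.97 to 3.72, and that library lies more than 1 log2 from the parental mean for Mycn, Dynap, Nrep, Col4a1, Col4a2 and Gem.

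Of 18193 genes, 6547 (36.0%) were called, 3013 higher and 3534 lower in tumour lines. Of these, 1611 differed by at least 2-fold, 896 higher and 715 lower. All tumour lines lay on one side of all parental arrays for 8076 genes (44.4%), where chance gives 5.71%. The median difference of all genes was 0.013. Without parental array 1, which moved the total most among the arrays left out, 5030 genes were called, and 4995 of them were among the 6547. With the library labelled GFP-transfected pooled with the parental arrays, the calls of 13 named genes ended, among them Shmt1 (then 0.53), Tgfb2 (-0.81), Smtn (0.75), Synpo2 (-0.22), Ddc (-0.84), Egr3 (-1.4), Fosl1 (1.21), Birc5 (0.34) and Cdh11 (-3.28).

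Among the anchor genes, the MYC family member Myc rose from 8.64 ± 0.12 to 9.90 ± 0.52 (1.26, SE 0.25, limma adjusted p = 0.00443). The neuroblastoma receptor kinase gene Alk rose by 0.64 (SE 0.09), from 5.17 ± 0.16 to 5.82 ± 0.05, and was low in both groups. Against the library labelled GFP-transfected Alk differed by 0.35 (SE 0.13) and was not called. Mki67, a marker of dividing cells, fell by 0.60 (SE 0.09). The tumour suppressor gene Cdkn2a was high in both groups, 12.26 ± 0.13 and 12.34 ± 0.25, and was not called. Sox10, a neural crest transcription factor gene, stood at 7.34 ± 0.13 and 7.42 ± 0.03. The sympathetic genes Hand2 (4.73 ± 0.03 and 4.83 ± 0.03) and Th (5.08 ± 0.19 and 5.19 ± 0.04) and the neurotrophin receptor gene Ngfr (5.40 ± 0.15 and 5.36 ± 0.19) were low in both, though above the trpnX controls, and were not called.

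Genes of cholesterol synthesis fell almost throughout. Of 17 measured, 0 rose and 16 fell (17 adjusted over the list alone), with a median difference of -1.84. The sterol enzymes Msmo1 (-3.00, SE 0.14), Hmgcs1 (-2.27, SE 0.16) and Cyp51 (-2.14, SE 0.07) moved most. Limma's camera gave an adjusted p of 3.54e-12, and adjusted p = 0.213 with an estimated correlation.

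Interferon-response genes rose. Of 19 measured, 17 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 2.38. Examples were Usp18, which removes ISG15 from proteins (4.87, SE 0.56), Rtp4 (3.96, SE 0.31) and the RNA-sensing enzyme gene Oas1a (3.59, SE 0.42). The list medians of tumour lines 3, 4, 5 and 6 against the parental mean were 1.30, 2.28, 3.84 and 2.90. Camera gave an adjusted p of 2.35e-07, and adjusted p = 0.494 with an estimated correlation. Genes of MHC class I antigen presentation rose too, 12 of 13 measured, while 1 fell (12 and 1 adjusted over the list alone), with a median of 1.32. The immunoproteasome subunit gene Psmb8 rose by 4.70 (SE 0.22), and the class I heavy chain genes H2-K1 and H2-D1 by 3.79 (SE 0.15) and 3.68 (SE 0.15). Pdia3, a chaperone of the loading complex, fell by 0.47 (SE 0.08). The camera adjusted p was 1.35e-06, and adjusted p = 0.343 with an estimated correlation. Beside these lists, the 18 markers of macrophages and leukocytes had a median difference of 0.07. Of these, 3 rose and 0 fell (3 and 0 adjusted over the list alone), namely Cd14 (1.83, SE 0.15), Cd68 (0.80, SE 0.09) and Lyz2 (0.49, SE 0.10), with a camera adjusted p of 0.195.

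Targets of p53 and inhibitors of cyclin-dependent kinases were mostly lower. Of 20 measured, 14 fell and 3 rose (16 and 3 adjusted over the list alone), with a median of -0.91. The receptor gene Eda2r (-2.84, SE 0.12) and the kinase inhibitor gene Cdkn1a (-2.57, SE 0.09) fell, whereas Perp, which encodes a membrane protein of desmosomes, rose by 4.09 (SE 0.31). Perp was also 3.85 higher in the library labelled GFP-transfected than in parental arrays, so its rise was not particular to the tumour lines. Camera gave an adjusted p of 1.07e-05, and adjusted p = 0.162 with an estimated correlation. Genes of mitosis fell as well, 12 of 24, with 1 higher (13 and 1 adjusted over the list alone) and a median of -0.43. The spindle checkpoint kinase genes Bub1b (-1.50, SE 0.11) and Bub1 (-1.0, SE 0.12) and the kinesin gene Kif20a (-1.01, SE 0.10) were lower, and Birc5, a chromosomal passenger protein gene, was higher (0.42, SE 0.10, adjusted p = 0.012). The list's camera adjusted p was 0.00117, and adjusted p = 0.343 with an estimated correlation. Without parental array 3 the rise of Birc5 was not called (0.34, adjusted p = 0.0548, within a range of 0.00279 to 0.0556 over the alternatives). Of 24 genes of DNA replication, 2 rose and 5 fell (2 and 4 adjusted over the list alone), Cdc6 by 0.71 (SE 0.09) and Pole by -0.49 (SE 0.09) among them, and the list was not called (camera adjusted p = 0.843).

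Metabolic genes that MYC proteins are known to activate were lower rather than higher. Of 21 measured, 11 fell and 3 rose (11 and 3 adjusted over the list alone), with a median of -0.33. The pyrimidine synthesis gene Cad (-1.08, SE 0.17), the glutamine transporter gene Slc1a5 (-1.06, SE 0.09) and the purine synthesis gene Gart (-0.95, SE 0.08) fell, and Shmt1 of the folate cycle rose by 0.71 (SE 0.11). Some other probe sets of Gart (-0.01 and -0.13) and of Shmt1 (0.2) were not called. Shmt1 was also 0.73 higher in the library labelled GFP-transfected than in parental arrays, so its rise was not particular to the tumour lines. The camera adjusted p was 0.00567, and adjusted p = 0.343 with an estimated correlation. Among genes above the median level it was 0.0584 with the same median of -0.33, within a range of 0.000218 to 0.343 over the alternatives. Of 27 ribosome biogenesis genes, 3 rose and 6 fell (3 and 6 adjusted over the list alone), with a median of -0.09. Rrp9 (-1.27, SE 0.11), the nucleolar protein gene Ncl (-1.01, SE 0.08) and the RNA polymerase I subunit gene Polr1b (-0.89, SE 0.15) fell, and the list was not called (camera adjusted p = 0.272). It was called with the library labelled GFP-transfected pooled with the parental arrays (median -0.22, adjusted p = 0.00619, within a range of 0.00619 to 0.685 over the alternatives). In the MYC family list, 5 of 12 rose and 2 fell (5 and 3 adjusted over the list alone). Its median was -0.04 while its mean was 0.66 and camera's direction was up (adjusted p = 0.419), and the median turned to 0.01 when arrays were normalized again. The list includes the transfected gene Mycn, whose rise of 6.74 was its largest change and weighs on that mean. The MYC antagonist gene Mxi1 fell by 0.95 (SE 0.09). JoMa1 carries a tamoxifen-activated fusion of MYC, and whether each group was grown with tamoxifen is not given in the sources used here. The levels of MYC targets are therefore relative to parental cells whose MYC activity is not known here.

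Many Hox genes and several imprinted genes fell. Of 26 Hox genes measured, which set position along the body axis, 15 fell and 2 rose (16 and 2 adjusted over the list alone), with a median of -1.0. Beside Hoxa9, Hoxa5 fell by 4.82 (SE 0.22) and Hoxb3 by 3.87 (SE 0.56), while Hoxd9 rose by 2.61 (SE 0.22). Camera gave an adjusted p of 0.000152, and adjusted p = 0.343 with an estimated correlation. Of 19 imprinted genes, 9 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.30. Dlk1 (-4.74, SE 0.11), Peg3 (-4.25, SE 0.11) and Mest (-3.67, SE 0.46) fell, and Impact rose by 0.95 (SE 0.10). Some other probe sets of Peg3 (-0.1 and -0.06) were not called. The camera adjusted p was 0.00559, and adjusted p = 0.343 with an estimated correlation. It was not called among genes above the median level, where the median was larger (-1.3, adjusted p = 0.0929), nor with the library labelled GFP-transfected pooled with the parental arrays (-0.09, adjusted p = 0.224), within a range of 5.74e-05 to 0.343 over the alternatives.

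Targets of TGF-beta and BMP signalling rose, 9 of 15 measured, and 3 fell (9 and 4 adjusted over the list alone), with a median of 0.75. The transcription regulator gene Id2 (3.79, SE 0.12), the inhibitory Smad gene Smad6 (3.18, SE 0.14) and the matricellular protein gene Ccn2 (2.65, SE 0.20) rose, and Tgfb2 fell by 1.19 (SE 0.12). Camera gave an adjusted p of 0.00575, and adjusted p = 0.213 with an estimated correlation. Of 14 smooth muscle genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.32. The contractile genes Cnn1 (5.04, SE 0.34), Actg2 (3.15, SE 0.38) and Smtn (1.07, SE 0.11) rose and Synpo2 fell by 0.49 (SE 0.10). In the library labelled GFP-transfected, Smtn (1.26) and Synpo2 (-1.1) differed from parental arrays in the same directions. The camera adjusted p was 0.0248, and adjusted p = 0.494 with an estimated correlation. Without tumour line 6 it was 0.0874, with a median of 0.23, within a range of 0.0068 to 0.494 over the alternatives. None of the 10 called lists changed the sign of its median when arrays were centred or normalized again.

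**Figure D3:**
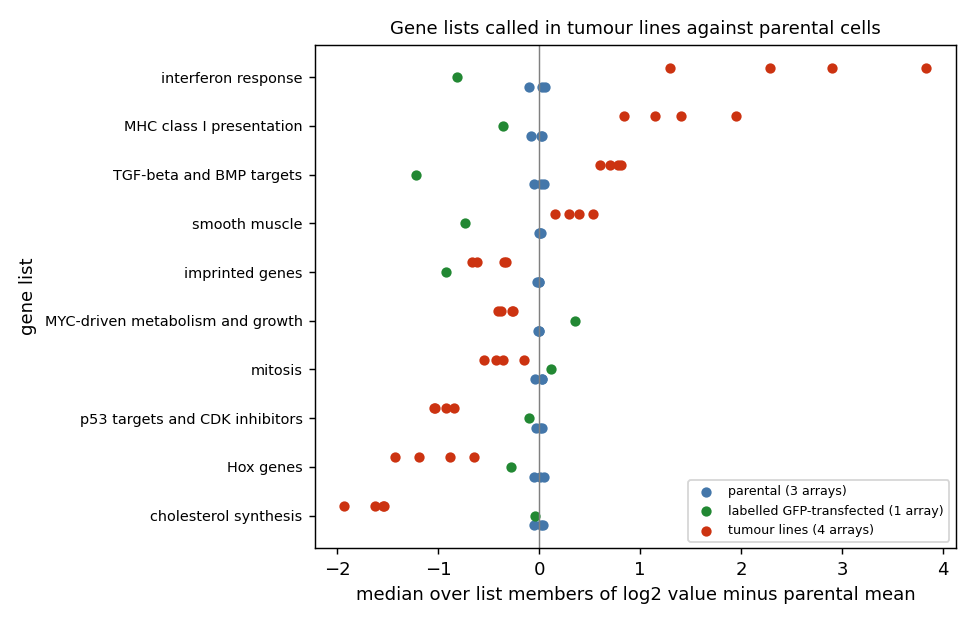
Median over the members of each called gene list (vertical axis) of the log2 value minus the parental mean (horizontal axis), with 1 point per array and 1 colour per group. The 4 tumour lines lie on the same side of the parental arrays in every list shown, from 1.30 to 3.84 for the interferon list, where the library labelled GFP-transfected lies at -0.82.

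Other lists were not called as a whole although single members changed strongly. In the fibroblast and collagen list, 10 of 21 rose and 4 fell (11 and 5 adjusted over the list alone), with Thy1 up by 4.0 (SE 0.47), Fbln2 by 3.02 (SE 0.61) and the collagen I chain gene Col1a2 by 2.99 (SE 0.34). Its median was 0.51 and its camera adjusted p 0.074. It passed the threshold without parental array 1 (0.0366), without tumour line 4 (0.0483), when arrays were centred (0.033) and with the library labelled GFP-transfected pooled with the parental arrays (0.0119, median 1.05), within a range of 0.000123 to 0.343 over the alternatives. Among matrix proteases and their inhibitors, 10 of 18 rose and 5 fell (11 and 7 adjusted over the list alone, median 0.68, camera adjusted p = 0.124), with Timp3 (4.14, SE 0.27), Mmp14 (3.46, SE 0.28) and Mmp3 (2.70, SE 0.16) highest. This list passed among genes above the median level (0.032, median 1.30) and with that pooling (0.0123, median 0.67), within a range of 0.00109 to 0.494 over the alternatives. Neural crest genes went both ways, 5 of 23 up and 4 down (6 and 4 adjusted over the list alone, camera adjusted p = 0.419). The crest transcription factor genes Tfap2b (-5.20, SE 0.13) and Zic1 (-4.48, SE 0.74) fell and the stem cell factor gene Sox2 rose by 3.81 (SE 0.46).

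Differentiation lists gave small counts. In the sympathoadrenal list 3 of 19 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.468), Cyb561 by 1.72 (SE 0.19) and the catecholamine enzyme gene Ddc by -1.23 (SE 0.12). Ddc also differed by -1.56 between the library labelled GFP-transfected and parental arrays. In the neuronal list 3 of 22 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.912), with the neuronal tubulin gene Tubb3 down by 3.73 (SE 0.10) and Map2 up by 2.55 (SE 0.21). Of 15 Schwann cell and glia genes 3 rose and 2 fell (3 and 2 adjusted over the list alone), Pmp22 by 0.94 (SE 0.10) and Pou3f1 by -2.90 (SE 0.33). That list had a median of 0.03, which turned to -0.002 when arrays were centred, a mean of -0.20, an upward camera direction (adjusted p = 0.843) and a downward fry direction. Of 11 melanocyte genes 1 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.453), the pigment cell regulator gene Mitf by 2.18 (SE 0.11). Mitf was also 2.36 higher in the library labelled GFP-transfected than in parental arrays. In the cartilage and bone list 3 of 11 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.843), with the phosphatase gene Alpl up by 3.90 (SE 0.32). Its median was -0.03, its mean 0.28, and camera and fry pointed up and down.

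Markers of endothelium, of erythroid, adipose and muscle tissue, and of epithelium moved little as groups. The smooth muscle and fibroblast lists above are also markers of cells that tumour-derived cultures could hold, and they did hold strong rises. Whether host stroma added to those rises was not tested. Of 14 endothelial markers 0 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.843), Egfl7 by -0.80 (SE 0.12). Of 12 erythroid, adipose and muscle markers 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.912), with a median of 0.02 that turned to -0.02 when arrays were centred, a mean of -0.05 and downward directions in camera and fry. Of 15 epithelial markers 0 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.468), with the desmosomal gene Dsp down by 2.28 (SE 0.37). Another probe set of Dsp differed by -0.01 and was not called. The female-specific transcript Xist read 13.21 ± 0.09 in parental cells and 12.97 ± 0.12 in tumour lines. The Y-linked genes Eif2s3y (3.78 and 3.84), Kdm5d (4.86 and 4.89) and Uty (4.56 and 4.54) were low in both, Eif2s3y at about the level of the trpnX controls. None of these 4 was called over all genes or adjusted over the list alone (camera adjusted p = 0.843). Xist had an adjusted p of 0.0543 in limma and was called without tumour line 4 (0.0337), when arrays were normalized again (0.0448), with the library labelled GFP-transfected pooled with the parental arrays (0.0341) and with another probe set (0.038), within a range of 0.0337 to 0.428 over the alternatives.

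Signalling and stress lists held strong single changes in both directions. Of 19 hypoxia genes 6 rose and 6 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.673), with the carbonic anhydrase gene Car9 up by 3.49 (SE 0.50). Of 16 Notch genes 2 rose and 6 fell (2 and 6 adjusted over the list alone, median -0.004, camera adjusted p = 0.435), Notch1 by -1.84 (SE 0.17) and its target Hes1 by -1.53 (SE 0.21), and this list was called among genes above the median level (median -1.306, adjusted p = 0.0281, within a range of 0.00334 to 0.811 over the alternatives). Of 15 Wnt targets 3 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.468), Sfrp2 by 3.65 (SE 0.52) and Lgr5 by -3.31 (SE 0.08). Another probe set of Lgr5 differed by -0.08 and was not called. Of 16 FGF and ERK targets 3 rose and 6 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.469), Fosl1 by 1.78 (SE 0.12) and Egr3 by -2.26 (SE 0.21). Of 16 pluripotency genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.843), Klf4 by 1.46 (SE 0.29) and Nanog by -1.14 (SE 0.08), with a median of 0.02 that turned to -0.02 when arrays were centred and directions of camera and fry that differed. Of 21 genes of the unfolded protein and amino acid stress responses 7 rose and 8 fell (8 and 8 adjusted over the list alone, camera adjusted p = 0.791), with the chaperone gene Dnajb9 up by 1.53 (SE 0.17) and Trib3 down by 1.51 (SE 0.21).

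The library labelled GFP-transfected served as the transfection control, although its Mycn signal goes against its label. Against parental JoMa1, the largest falls were those of the adhesion gene Cdh11 (-6.99, SE 1.45), the receptor kinase gene Epha3 (-6.83, SE 0.50), the matrix protein gene Postn (-6.59, SE 0.47), the smooth muscle actin gene Acta2 (-6.06, SE 0.17) and the collagen cross-linking enzyme gene Lox (-5.85, SE 0.18). Besides Mycn, the fetal serum protein gene Afp rose by 5.55 (SE 0.51), the C-type lectin gene Clec4d by 5.28 (SE 0.49), the kinase gene Mapk10 by 4.72 (SE 0.18) and the cytokine gene Il24 by 4.37 (SE 0.19). Other probe sets of Afp (-0.61) and Mapk10 (-0.06) went the other way without a call. Limma's adjusted p-values for these genes were 0.0133 or lower, with 1 array in the group assumed to vary like the others.

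By list, 18 of 21 fibroblast and collagen genes were lower in that library and 0 higher (18 and 0 adjusted over the list alone), with a median of -2.64. Lower medians were also found for targets of TGF-beta and BMP (-1.22, 8 lower and 1 higher of 15; 11 and 1 adjusted over the list alone), matrix proteases and inhibitors (-1.21, 10 lower and 2 higher of 18; 11 and 2 adjusted over the list alone) and imprinted genes (-0.92, 11 lower and 1 higher of 19; 12 and 1 adjusted over the list alone). Smooth muscle genes (-0.73, 6 lower and 1 higher of 14, 8 and 1 adjusted over the list alone) and interferon-response genes (-0.82, 4 lower and 0 higher of 19, 4 and 0 adjusted over the list alone) were lower too. Each of these 6 medians lay at percentile 0 of 10000 random lists. In contrast, 18 of 27 ribosome biogenesis genes were higher and 0 lower (23 and 0 adjusted over the list alone, median 0.57), among them Nop16 (1.09, SE 0.17) and Nolc1 (1.05, SE 0.22). Of 21 MYC-activated metabolic genes 6 were higher and 0 lower (6 and 0 adjusted over the list alone, median 0.35), such as Slc1a5 (0.89, SE 0.14). Both medians lay at percentile 100. None of these 8 medians changed sign when arrays were centred or normalized again, and genes and lists here are differences of 1 array.

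In that comparison 2927 genes (16.1%) were called, 1352 higher and 1575 lower, and 1046 of them differed by at least 2-fold. The split depended on scaling, since centring each array on its median moved all genes by 0.19 and gave 3022 higher and 1109 lower (73.2% higher, against 46.2%). With only the parental and GFP-labelled arrays in the fit, 4984 genes were called. Without parental array 3, 837 genes were higher.

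Set against the library labelled GFP-transfected, whose Mycn signal goes against its label, the tumour lines were higher in the detoxifying enzyme gene Mgst1 (8.42, SE 0.52), Abi3bp (7.81, SE 0.31), the metalloprotease inhibitor gene Timp3 (7.24, SE 0.39), the acute phase gene Saa3 (7.20, SE 0.23) and Lox (7.12, SE 0.18). They were lower in Bex1 (-9.75, SE 0.11), the homeobox gene Rhox5 (-6.94, SE 0.16), Slc38a4 (-6.58, SE 0.54), Serpinb2 (-6.42, SE 0.53) and Col4a1 (-6.04, SE 0.15). Limma's adjusted p-values were 5.32e-05 or lower. Mycn itself was higher by 2.43 (SE 0.12, 5.39-fold). Another Mgst1 probe set differed by -0.07. The library labelled GFP-transfected read 3.64 for Mgst1 and 3.83 for Abi3bp, at the level of the trpnX controls. The sizes of these differences are therefore understated.

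Fibroblast and collagen genes were higher in the tumour lines than in that library for 19 of 21 members, with 0 lower (20 and 0 adjusted over the list alone, median 3.84). So were 14 of 19 interferon-response genes (16 adjusted over the list alone, median 3.87), 12 of 13 MHC class I genes (12 adjusted over the list alone, median 2.37) and 12 of 15 targets of TGF-beta and BMP (12 adjusted over the list alone, median 1.56), each at percentile 100 of random lists. Cholesterol synthesis genes were lower for 15 of 17 (16 adjusted over the list alone, median -1.52) and ribosome biogenesis genes for 22 of 27 (25 adjusted over the list alone, median -0.68), each at percentile 0. These 6 medians kept their sign when arrays were centred or normalized again.

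In total 5514 genes (30.3%) were called against that library, 2538 higher and 2976 lower, and 2180 differed by at least 2-fold. Centring each array moved all genes by -0.23 and gave 1824 higher and 5208 lower (25.9% higher, against 46%), an alternative chosen after seeing the data. Of the genes called against parental cells, 1691 were higher and 1998 lower in both comparisons, where independent lists would share 420 and 578. The sign was the same for 86.6% of the calls, against 66.6% in simulations without effects. Of the same calls, 54.3% had the same sign in the library labelled GFP-transfected against parental, where such simulations gave 71.4%. In these simulations the shared sign comes from the noise of shared arrays alone. Neither simulated share is therefore a baseline for calls with real effects. In that pair 414 genes were higher and 666 lower in both, where independent lists would share 224 and 306, while 380 and 370 genes went opposite ways, where 261 and 263 would. Across genes, which are not independent replicates, the correlation of those differences was 0.098 against 0.378 simulated, and the covariance was 0.043 against 0.010. In a test chosen after seeing the data, the 4 tumour lines were split so that 2 were set against parental cells and the other 2 against that library. Over the 6 ways of doing so, 1380 to 1514 genes were higher and 1596 to 1795 lower in both, where independent lists would share 310 to 377 and 430 to 524, and the sign was the same for 84.19 to 86.88% of the calls. The 3 parental arrays shared by the other pair could not be split into sets of 2, so part of any excess there may come from them.

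The tumour lines differed from each other more than the parental arrays did. The genes with the largest SD over the 4 lines included Plac8, at 9.01, 8.60, 12.59 and 12.55 in lines 3 to 6, the ankyrin repeat gene Asb5, at 8.49, 6.26, 10.49 and 10.86, and the growth factor gene Epgn, at 11.07, 7.33, 11.72 and 9.47. The adhesion gene Cdh11 read 6.86, 10.50, 7.72 and 5.56 against 12.69 ± 0.01 in parental cells. The germ-cell gene Tex19.1 read 10.88, 11.36, 9.02 and 6.60, the metallothionein gene Mt1 5.45, 5.95, 9.93 and 6.08, Ppp1r9a 8.70, 8.76, 11.96 and 7.46, and the matrix proteoglycan gene Bgn 12.73, 9.24, 13.05 and 13.12. Against parental cells, Plac8, Asb5, Epgn and Bgn rose and Cdh11 fell, with limma adjusted p-values of 0.00746 or lower. The rise of Tex19.1 (3.10, SE 1.0, adjusted p = 0.0404) was not called when any array other than tumour line 6 was left out (differences of 2.47 to 3.25, adjusted p 0.0576 to 0.118, within a range of 0.00118 to 0.118 over the alternatives). The fall of Mt1 (-3.66, SE 0.95, adjusted p = 0.0165) was not called without parental array 1, 2 or 3, although the difference stayed at -3.62 to -3.69 (adjusted p 0.0548 to 0.0577, within a range of 1.02e-06 to 0.796 over the alternatives). Ppp1r9a differed by 2.55 (SE 0.89, adjusted p = 0.055) and was called without tumour line 5 (1.63, adjusted p = 0.0063) or 6 (3.13, adjusted p = 0.0213), with the library labelled GFP-transfected pooled with the parental arrays (2.82, adjusted p = 0.0368) and with other probe sets (1.06 and -0.40), within a range of 0.00361 to 0.616 over the alternatives.

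The root mean square difference over genes was 0.156 to 0.179 for the 3 pairs of parental arrays and 0.302 to 0.390 for the 6 pairs of tumour lines. It was 0.602 to 0.609 between parental arrays and the library labelled GFP-transfected, and 0.742 to 0.834 for the 12 pairs of parental and tumour-line arrays. The median SD of a gene was 0.08 in parental arrays and 0.128 in tumour lines, and 121 genes had an SD over 1 in tumour lines against 0 in parental arrays. No test was made of this difference.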

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

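The values of single tumour lines and of probe sets without a gene name were looked for by rules set before the data were examined, as was the count over splits of the arrays, while the tests of the Mycn signal were written after the result was seen.

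Single tumour lines stood apart from the other 3 in 10 items. The homeobox gene Hoxa9 read 8.08 in line 4 and 4.95 to 5.21 in the others, and the matrix proteoglycan gene Bgn read 9.24 in line 4 against 12.73 to 13.12. Perp, a desmosome gene, read 9.27 in line 4 against 10.43 to 10.50, and the macrophage marker gene Cd68 read 6.30 there against 6.58 to 6.62. In line 5 the metallothionein gene Mt1 read 9.93 against 5.45 to 6.08, Id2 11.41 against 11.81 to 11.84, Birc5 11.83 against 12.11 to 12.15 and Ngfr 5.08 against 5.43 to 5.47. Lox read 13.52 in line 6 against 13.04 to 13.12, and Sox10 read 7.47 in line 3 against 7.40 to 7.41. In each case the distance to the nearest line was, as a share of the range over the 4 lines, above Dixon's critical value. Of 169 items checked 10 did so, and chance gives about 1 in 20.

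Probe sets without a gene name were left out of every comparison, and 1244 of 9160 were called between tumour lines and parental arrays (limma, Benjamini-Hochberg over these probe sets), 389 higher and 855 lower. A probe set with one of the largest falls read 10.34 ± 0.15 in parental and 4.64 ± 0.43 in tumour-line arrays, and one that rose read 8.26 ± 0.09 and 11.46 ± 0.19. Both were chosen after their values were seen.

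The 7 parental and tumour-line arrays can be split into 4 and 3 in 35 ways. Only 1 of them, the real one, gave as many called genes, 6547, and the highest of the others gave 4. The arrays thus separate by group. Nothing states that the parental arrays came from separate cultures, so the splits cannot tell a group effect from a difference between cultures. If the tumour lines share a transfected stock, the splits cannot separate a group effect from that stock either.

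The library labelled GFP-transfected carried a high Mycn signal. Tumour-line RNA mixed into it would need a share of 17.7% and would raise 76 genes that are low in parental and at least 8-fold higher in tumour-line arrays by a median of 1.88, but their median was -0.03, which argues against mixing. A rise of the cells' own full-length Mycn transcript is argued against by the Mycn probe set that is bright in parental cells, which differed by -3.80. The rise of 4.31 in the probe set that also rises in the tumour lines is the observation itself and does not test for a MYCN construct. Whether a construct reached the control cells or the label is wrong stays open.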

How the results depend on the processing

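Centring in the comparison of tumour lines with the library labelled GFP-transfected, and leaving that library out of the fit, were chosen after seeing the data. The second left 6547 genes and 10 lists by its construction. Tumour lines against parental gave 5030 to 6649 calls when 1 array was left out, of which 4995 to 6123 were among the 6547, with 2303 to 3059 higher and 2727 to 3590 lower. Other settings gave 4558 (adjusted p under 0.01) to 7621 (every probe set tested singly), and a minimum of 2-fold left 1611, 896 higher and 715 lower, since it only removes calls. Of the calls shared with the 6547, counted in all settings but the limits on p and fold and the single probe sets, all had the same direction except 3 with the mean of probe sets and 2 without _x_at and _s_at probe sets. The library labelled GFP-transfected against parental gave 1982 to 2048 calls without 1 parental array, 837 to 918 higher, the lowest without parental array 3. Fitting those arrays alone gave 4984, 2466 higher and 2518 lower; the cause was not tested. Centring gave 3022 higher, and 5208 lower in tumour lines than in that library, since it moved all genes by 0.19 and -0.23 by its construction. Of the lists, 10 were called, 0 with an estimated correlation and 21 with fry, which asks another question, and 9 to 11 without 1 array. Over 32 lists, 408 of 441 alternatives stayed on the same side of the threshold, but in 45 of these, all of lists not called, the median had the other sign. Over 145 named results, 1427 of 1511 stayed, 4 with the other sign. Other probe sets reversed 10 of these, Mycn (-3.53, and -3.80 in the library labelled GFP-transfected), Ppp1r9a (-0.40), Ddc (0.06), Fabp4 (0.10), Egr3 (0.07), Impact (-0.15), Afp (-0.61), Mapk10 (-0.06) and Mgst1 (-0.07). In 29 further cases another probe set kept the sign but lost the call, among them those of Rgs2, Gart, Dsp, Lgr5 and Peg3. The cause was not tested. The spread of parental arrays was 0.173, 0.156 to 0.179 without 1 array and 0.12 among genes above the median level, and that of tumour lines was 0.319, 0.311 to 0.333 without 1 array and 0.282 with the mean of probe sets; the cause was not tested. No paired analysis was made, because the array and tumour numbers are not stated to mark pairs. Signal over background limits genes near the control level of 3.84 to 4.04, whose differences are understated.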

Other observations

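The tests of neighbouring genes and of the interferon list were written after the result was seen, and the genes of this part were chosen after their values were seen.

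Genes that lie next to each other moved together in the tumour lines. Along the gene order of GRCm38.p6, 50 expressed genes from Adgre5 to Heatr3 had a median difference of 1.72 against parental arrays, with 45 called higher and 2 lower, where 23% of all genes used were higher. Among them were the transcription factor gene Junb (3.22, SE 0.19), the glutamate receptor accessory gene Neto2 (4.24, SE 0.22), the calcium channel gene Cacna1a (3.19, SE 0.09), the histone chaperone gene Asf1b (2.51, SE 0.07) and the replication origin gene Orc6 (2.06, SE 0.09). The chaperone gene Calr, a member of the MHC class I list, lies there too (0.64, SE 0.07), and Adgre5 fell by 1.29 (SE 0.20). In the library labelled GFP-transfected the median over the run was -0.09. A shorter run of 15 genes from Bcap31 to Lage3 had a median of 0.91.

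JoMa1 cells are known to carry a tamoxifen-activated fusion of MYC to the oestrogen receptor. The brightest Esr1 probe set read 10.93 ± 0.01 in parental arrays, 11.13 in the library labelled GFP-transfected and 10.94 ± 0.22 in tumour lines. Of the other Esr1 probe sets, one rose from 4.51 ± 0.20 to 6.56 ± 0.65 (limma adjusted p = 0.000958) and one from 5.32 ± 0.17 to 7.83 ± 1.02 (limma adjusted p = 0.00323).

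The run from Adgre5 to Heatr3 was set against chance order. With a window of 25 genes, the farthest running median was 1.89, and 0 of 1000 shuffles of the 9913 genes used reached it, the farthest at 0.74. The run was not the work of 1 tumour line alone, since the line medians were 1.87, 1.54, 1.86 and 1.61, the lowest being 1.54. Extra DNA copies of this stretch, present in all 4 lines, may explain why 90% of its genes were higher, but no DNA was measured, so that copies and a shared change in regulation cannot be told apart.

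The rise of interferon and MHC class I genes was set against host leukocytes carried into the cultures. Leukocyte markers had a median difference of 0.07, and the highest, Cd14, reached 1.83, below the interferon median of 2.38. Cd68 (0.80) and Lyz2 (0.49) were called higher too, and 0 of the 18 markers were called lower. Fry called the list upward (adjusted p = 0.00581), while camera did not call it (adjusted p = 0.195). The small median argues against such cells as the main source of the rise, but a small share of them is not excluded. Laptm5, Cd14 and Csf1r read 8.32, 7.43 and 7.05 in parental arrays, so that 3 of the 18 markers read above 7 in JoMa1 itself. A shift that moves all genes of an array alike could not raise these lists and lower another. The median of the cholesterol synthesis list fell in each of the 4 lines, the smallest fall being -1.54. That fall was known before the test was written, so it describes these arrays and is no independent test. A further 2 tests of such a shift were left out because the normalization fixes their outcome. Interferon signalling within the tumour lines, culture conditions and passage through the host stay open.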
